A study of Homo sapiens with 4 samples.

How the data were processed

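RNA was sequenced from MDA-MB-231, an established human breast cancer line that lacks oestrogen receptor, progesterone receptor and HER2 amplification. Per the labels, 2 libraries came from cells given the solvent DMSO and 2 from cells given Rib_GW, which the series title calls a derivative of ribociclib, an inhibitor of the cell cycle kinases CDK4 and CDK6. Exposure lasted 24 h per the labels' protocols, and the dose is not given in the sources used here. The treatment protocol writes the compound as Rib_CA while every title and treatment label writes Rib_GW; groups were taken from the titles. Per the labels' protocols, total RNA went into a dual-mode mRNA library kit for Illumina sequencing.

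The deposited values are counts, whole numbers of reads per Ensembl gene with no normalization, in 1 table with 1 column per library. The submitters' processing notes name the builds GRCh38, GRCm38 and mm10 with no role for each, although the gene identifiers are human. The aligner, the counting program, the annotation and the strand setting are not given in the sources used here, so reads of overlapping genes cannot be assigned to one strand with certainty. The table held 20263 genes, of which 4037 had no count in any library and 19840 matched a gene name. Library totals were 34774542 and 37754168 counts for DMSO replicates 1 and 2, and 36983632 and 46961958 for Rib_GW replicates 1 and 2. A count of 0 allows up to 3 counts, or between 0.0639 and 0.0863 CPM (counts scaled to the library total) by library. Wilson 95% intervals on the shares of counts were at most 0.0131 percentage points to either side. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

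Low counts were removed with edgeR's filterByExpr (minimum count 10), which left 13671 genes, 13490 of them named. Libraries were scaled by TMM, and Rib_GW was compared with DMSO by edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust fit, two-sided, treatment as the only term) with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are TMM-scaled CPM, given as mean ± SD. The labels name replicates but no separate cultures, so p-values of single genes measure only the spread between these libraries, which may be technical. Gene positions, transcript lengths, GC content and exon overlaps came from GENCODE release 29 on GRCh38. Transcript length and GC content are those of the longest annotated transcript of each gene, which may not be the one expressed.

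A total of 33 gene lists were fixed before the data were examined, covering the cell cycle, apoptosis, stress responses, metabolism, inflammation and markers of other cell types. The lists were the CDK4/6-RB axis, DNA replication and E2F targets, G2/M and mitosis, DNA repair, replication-dependent histones, the pro-apoptotic and anti-apoptotic BCL2 families, apoptosome and caspases, death receptors and ligands, p53 targets, the unfolded protein response, the ATF4 and integrated stress response, heat shock, NRF2 and oxidative stress, metallothioneins, cholesterol synthesis, fatty acid synthesis, lysosome, autophagy, cytosolic ribosomal proteins, ribosome biogenesis and MYC targets, nuclear-encoded oxidative phosphorylation and mitochondrially encoded mRNAs. The others were NF-kB and inflammatory cytokines, interferon response, antigen presentation, immediate early and MAPK response, hypoxia and glycolysis, senescence-associated secretion, epithelial-mesenchymal transition (EMT) and extracellular matrix, and markers of luminal breast epithelium, of blood cells and of fibroblasts and endothelium. Each list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists, and with fry, which asks whether the members move on balance one way. At the preset correlation, camera compares members with the other genes, and its degrees of freedom come from the number of genes. Those p-values take genes as nearly independent and do not measure the spread of a list between libraries. With an estimated correlation, camera's test rests on the residual degrees of freedom (libraries beyond the number of groups), which are few with 2 libraries per group. A call lost there therefore says little about correlation between genes. Member calls were counted over all genes tested and again adjusted over the list alone.

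The genes named in the text follow a rule fixed beforehand. It takes the 8 largest increases and 8 largest decreases past the threshold with at least 10 CPM in the higher group and no overlap between groups. It adds up to 4 called members of each list with at least 1 CPM, or the 2 with the smallest p where none was called, and 18 genes of the cell cycle and of apoptosis whatever their values, 1 of which is not reported here. The alternatives planned beforehand were RLE and upper-quartile scaling, no filter and a filter at 10 CPM, the DESeq2 1.42.0 Wald test, limma-voom, a 2-fold minimum, each library left out in turn (the lone library of that group is assumed to vary like the other group), a block for the replicate number, and an estimated correlation in camera. Those chosen after seeing the data were a length and GC correction (loess span 0.3), removal of mitochondrially encoded genes, an adjusted p of 0.10 and a crossed block. Counts were simulated from the real means and library sizes to test the comparison of Rib_GW with DMSO, with 13515 genes fitted and 50 genes changed at each of 4 fold sizes. The test recovered 12% of genes changed 2-fold, 84% changed 4-fold, 98% changed 8-fold and 100% changed 16-fold. It made 21 false calls among 173, a larger share than the threshold on adjusted p is set to allow. Calls in the real libraries may therefore include more false ones than that threshold implies. In the simulation, 94.7% of estimates lay within 2 standard errors of the simulated value. The 173 calls also include members of the cholesterol synthesis list, which was raised 2-fold in the simulation. No library was left out of the comparison.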

Results

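The transcriptome of MDA-MB-231 breast cancer cells was measured by RNA sequencing after 24 h with Rib_GW or with DMSO, in 2 libraries per group. The series title names Rib_GW as a derivative of the CDK4/6 inhibitor ribociclib and the endogenous apoptotic pathway as its subject, and the design asks how treated cells differ from DMSO controls. Totals ran from 34774542 counts in DMSO replicate 1 to 46961958 in Rib_GW replicate 2. Across genes, log2 CPM correlated at a Pearson r of 0.976 between the DMSO libraries, 0.956 between the Rib_GW libraries, and 0.899 to 0.946 between groups (genes are not independent replicates). Rib_GW replicate 1 lay farther from the DMSO mean than replicate 2, with a median absolute log2 difference over genes of 0.716 against 0.456.

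After Rib_GW 102 genes rose and 101 fell among the 13671 tested, and each of these changes was at least 2-fold. IL24, a secreted cytokine, rose from 0.437 ± 0.190 to 37.5 ± 35.6 CPM (SD, n = 2 per group), a log2 fold change of 6.42 (SE 0.82), with 62.7 and 12.4 CPM in the Rib_GW libraries. DUSP15, a dual-specificity phosphatase, rose from 0.442 ± 0.353 to 10.3 ± 3.87 CPM, and HSPA6, a stress-inducible chaperone, from 1.94 ± 0.407 to 31.6 ± 12.5 CPM. The other large increases were SH3TC1 (log2 fold change 3.90, SE 0.30), the kinase STK32A (3.86, SE 0.52), the neutrophil-attracting chemokine CXCL2 (3.60, SE 0.53) and HES7, a transcriptional repressor in Notch signalling (3.58, SE 0.40). The read-through gene PTGES3L-AARSD1 was also called at 4.21 (SE 0.59), but 53.2% of its exonic length overlaps another gene, so its level is uncertain. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, called genes had adjusted p from 0.0423 up to just under the threshold of 0.05, another 1647 genes lay between 0.05 and 0.10, and 3880 had an unadjusted p under 0.05. The groups did not overlap in 8462 genes (61.9%). Over all ways to split the libraries 2 against 2, the average share is 33.3%. Genes are not independent and shift together between libraries, so the difference between these shares was not tested.

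Among the decreases, FAM111B, a protease linked to DNA replication, fell from 94.9 ± 45.0 to 4.60 ± 3.90 CPM (n = 2 per group; log2 fold change -4.36, SE 0.64). SERTAD4 fell from 60.3 ± 6.11 to 3.94 ± 0.987 CPM, and CCNE2, the cyclin E2 that partners CDK2 at S phase entry, from 61.1 ± 2.63 to 4.32 ± 3.58 CPM. LFNG, a glycosyltransferase acting on Notch receptors, had a log2 fold change of -3.73 (SE 0.39), and E2F2, a transcription factor of S phase genes, one of -3.45 (SE 0.35). On the log2 scale, INHBB, the beta B subunit of activins and inhibins, fell by 3.23 (SE 0.29), the secreted protein ISM1 fell by 3.16 (SE 0.41) and WDR76 fell by 3.08 (SE 0.38). Of CCNE2's exonic length, 37.0% overlaps another gene.

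On GRCh38, IL24 (ENSG00000162892) spans 206897443 to 206904139 of chromosome 1 and HSPA6 (ENSG00000173110) spans 161524540 to 161526910 of the same chromosome. DUSP15 (ENSG00000149599) lies at 31847637 to 31870747 of chromosome 20. FAM111B (ENSG00000189057) lies at 59107185 to 59127410 of chromosome 11, SERTAD4 (ENSG00000082497) at 210232799 to 210246631 of chromosome 1, and CCNE2 (ENSG00000175305) at 94879770 to 94896678 of chromosome 8. Each is annotated as protein-coding.

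The number of called genes differed with the libraries in the fit. Each fit without a library leaves 1 library in its group, which is assumed to vary like the other group, whose libraries alone give the spread. Here and below, calls in these fits show only how far a value depends on single libraries. Called genes were chosen for their change in these same libraries, so a direction kept in such a fit is no independent support. Called genes numbered 135 without DMSO replicate 1, 28 without DMSO replicate 2, 977 without Rib_GW replicate 1 and 4426 without Rib_GW replicate 2, and all 203 genes kept their direction in each of these fits. Of the genes described above, CXCL2 was no longer called without DMSO replicate 1. IL24, PTGES3L-AARSD1, STK32A, CXCL2, HES7, FAM111B, CCNE2, ISM1 and WDR76 were no longer called without DMSO replicate 2, with edgeR adjusted p from 0.0531 to 0.0939. Limma-voom also left IL24, PTGES3L-AARSD1, STK32A and CXCL2 uncalled, at adjusted p from 0.0538 to 0.0599. The DESeq2 Wald test called 2313 genes, edgeR without a filter on low counts 927, upper-quartile scaling 369 and RLE scaling 358.

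**Figure D1:**
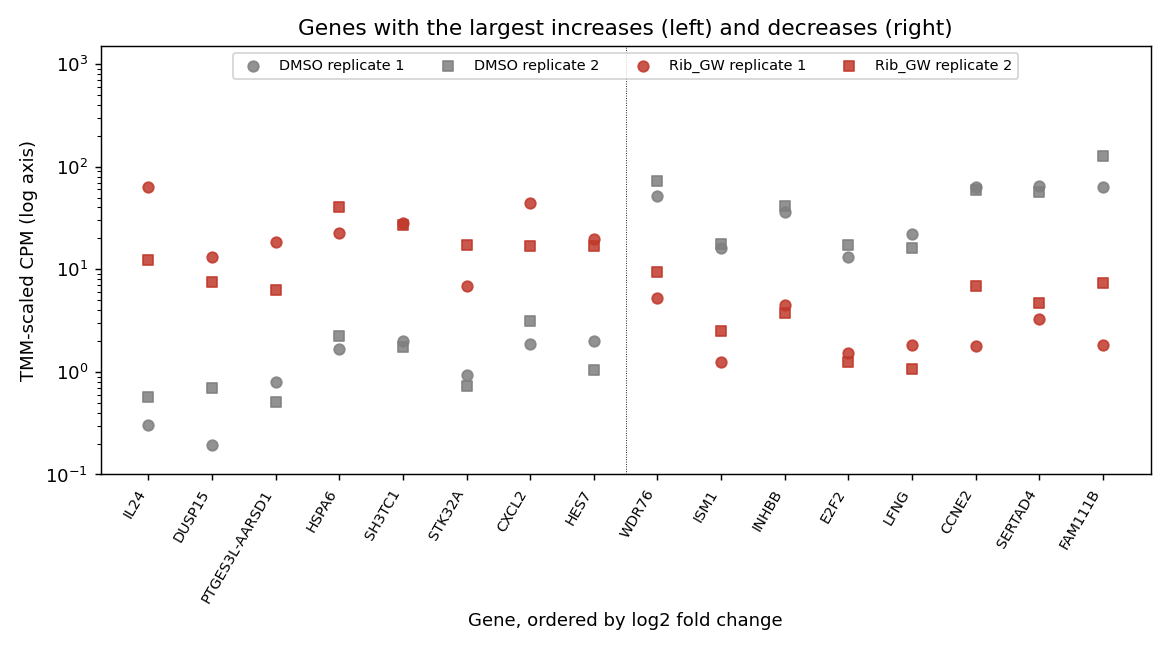
TMM-scaled CPM (log axis) of the 8 largest increases and the 8 largest decreases after Rib_GW, with 1 point per library (grey DMSO, red Rib_GW; circles replicate 1, squares replicate 2). In each gene the DMSO and Rib_GW libraries do not overlap, and the Rib_GW libraries of IL24 lie at 62.7 and 12.4 CPM.

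Lists of S phase and mitotic genes were lower after Rib_GW at camera's preset correlation. All 40 measured DNA replication and E2F targets had a negative log2 fold change, with a median of -1.19. Of these, 6 fell and 34 did not pass, and 26 fell when adjusted over the list alone. MCM10, a replication initiation factor, fell from 73.0 ± 0.459 to 9.88 ± 5.11 CPM (n = 2 per group). UHRF1, which maintains DNA methylation, fell by 2.32 (SE 0.26) on the log2 scale, the helicase subunit MCM4 fell by 2.08 (SE 0.26) and MCM3 fell by 1.97 (SE 0.31). The list was lower in camera (adjusted p = 8.65e-17), but not called at adjusted p = 0.583 with an estimated correlation. Of 40 G2/M and mitosis genes (median -1.19), 2 fell, and 22 fell when adjusted over the list alone. KIF20A, a mitotic kinesin, fell from 181 ± 0.603 to 48.1 ± 0.931 CPM, and CCNA2, cyclin A2, fell by 1.61 (SE 0.27) on the log2 scale. This list had a camera adjusted p = 2.73e-11 and an adjusted p = 0.583 with an estimated correlation.

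The CDK4/6-RB axis held 2 falling members, E2F2 and CCNE2, among 21 measured, 19 did not pass, and its median was -0.78. Adjusted over the list alone, 4 rose and 11 fell. Its camera adjusted p = 0.00245, against an adjusted p = 0.583 with an estimated correlation. CDK4 itself had a log2 fold change of 1.12 (SE 0.35, edgeR adjusted p = 0.113, 43.2% of its exonic length shared with a neighbour), and CDK6 one of -0.66 (SE 0.37, adjusted p = 0.289). CCND1, the cyclin D1 that activates both kinases, was at 894 ± 101 CPM in DMSO and 371 ± 7.86 CPM in Rib_GW (edgeR adjusted p = 0.0603). RB1, their main substrate, was at -1.0 (SE 0.27, edgeR adjusted p = 0.0851), the proliferation marker MKI67 at -2.31 (SE 0.46, adjusted p = 0.0617), and the kinase inhibitor CDKN1A at 2.09 (SE 0.39, adjusted p = 0.0579). Among 14 alternatives, CDKN1A was called in 9, MKI67 in 7, CCND1 in 6, CDK4 and RB1 in 3 each and CDK6 in 1. CDK4 had a log2 fold change of 0.53 without Rib_GW replicate 1 and 1.51 without Rib_GW replicate 2, CDK6 ranged from -1.14 to -0.16, and RB1 was at -0.66 after the length and GC correction.

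None of 26 DNA repair genes passed (median -0.89), and 10 fell when adjusted over the list alone. XRCC2 had a log2 fold change of -1.71 (SE 0.35) and BARD1 one of -1.29 (SE 0.29), both in homologous recombination. The list was lower in camera (adjusted p = 5.82e-07), with an adjusted p = 0.653 with an estimated correlation. None of 13 replication-dependent histone genes passed (median -1.18), 1 fell when adjusted over the list alone, and H2BC12 and H2AC6 had values of -1.28 (SE 0.29) and -1.44 (SE 0.42). Camera gave an adjusted p = 0.00474 for the histones, and an adjusted p = 0.653 with an estimated correlation.

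The count of falling members in these lists moved with single libraries. Without DMSO replicate 1, DMSO replicate 2, Rib_GW replicate 1 and Rib_GW replicate 2 in turn, 4, 0, 17 and 27 DNA replication genes fell, 0, 0, 13 and 27 mitotic genes, and 0, 0, 6 and 21 repair genes. The CDK4/6-RB axis had 2, 1, 8 and 11 falling and 1, 0, 2 and 4 rising members in those fits. MCM3, KIF20A and CCNA2 were not called when either DMSO library was left out, and CCNE2, MCM10, UHRF1 and MCM4 were not called without DMSO replicate 2. With limma-voom CCNA2 was not called (adjusted p = 0.0502). Without Rib_GW replicate 2 the repair list had a median of -1.52, and the histone list was not called (camera adjusted p = 0.224, median -0.72).

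Of the apoptosis genes fixed by name and reported here, only BBC3 passed the test. BBC3, which encodes the BH3-only protein PUMA, rose from 5.37 ± 0.273 to 30.1 ± 3.74 CPM (n = 2 per group; log2 fold change 2.49, SE 0.29, edgeR adjusted p = 0.0423). The gene (ENSG00000105327) lies at 47220822 to 47232766 of chromosome 19 on GRCh38. The effectors of mitochondrial pore formation did not pass, with BAX at 0.28 (SE 0.29, edgeR adjusted p = 0.550) and BAK1 at 1.27 (SE 0.36, adjusted p = 0.0970). Among other BH3-only genes, PMAIP1 had a log2 fold change of 0.89 (SE 0.38) and BCL2L11 one of -1.31 (SE 0.45). The survival genes BCL2 (-0.67, SE 0.34), BCL2L1 (-0.22, SE 0.28), MCL1 (0.78, SE 0.27) and BCL2L2 (2.39, SE 1.17) did not pass either. BCL2L2 was at 4.05 and 2.38 CPM in the DMSO libraries and 32.6 and 1.28 CPM in the Rib_GW libraries. Of its exonic length 19.4% overlaps another gene, as does 43% of that of BCL2L1. The apoptosome components APAF1 (0.00, SE 0.30) and CYCS (0.02, SE 0.36) and the initiator caspase CASP9 (0.17, SE 0.40) lay near 0. BBC3 was not called without DMSO replicate 1 (edgeR adjusted p = 0.0723) or DMSO replicate 2 (adjusted p = 0.128), within a range of 3.21e-09 to 0.128 over its alternatives. Without Rib_GW replicate 1, PMAIP1 had a log2 fold change of 0.22, BAK1 of 0.68 and BCL2L2 of -1.37, and without Rib_GW replicate 2 PMAIP1 was at 1.32 and BAK1 at 1.66, both past the threshold in that fit of 1 Rib_GW library. Over the alternatives BCL2L11 ranged from -1.81 to -0.62, BCL2 from -1.0 to -0.29, BCL2L1 from -0.45 to 0.00 and BAX from -0.23 to 0.46.

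**Figure D2:**
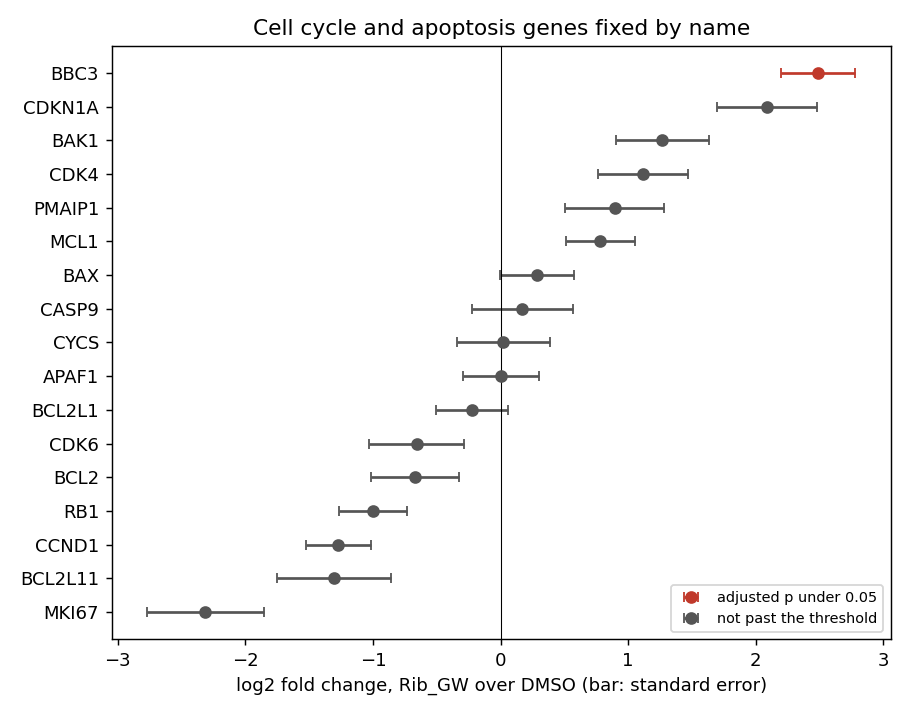
Log2 fold change of Rib_GW over DMSO for 17 cell cycle and apoptosis genes fixed by name, with bars of 1 standard error (red, past the threshold; grey, not past it). BBC3 at 2.49 is the one gene past the threshold, and APAF1, CYCS and CASP9 lie within 1 standard error of 0.

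As groups, the pro-apoptotic BCL2 family had 1 rising member, BBC3, and 9 not past the test among 10 (median 0.78). Adjusted over the list alone, 4 rose and 1 fell. Its camera adjusted p = 0.0490 turned into an adjusted p = 0.653 with an estimated correlation, and it was also not called without DMSO replicate 1 (adjusted p = 0.123) or Rib_GW replicate 1 (adjusted p = 0.157), where the median was 0.33. Nor was it called with upper-quartile scaling (adjusted p = 0.0520), the 10 CPM filter (0.0658), DESeq2 (0.0757), limma-voom (0.0790), the length and GC correction (0.347, median 0.33) or without mitochondrially encoded genes (0.0516). Its median was 1.19 without Rib_GW replicate 2, where 4 members rose, and none rose without either DMSO library. None of 4 anti-apoptotic BCL2 genes passed over all genes or adjusted over the list alone (median 0.28, camera adjusted p = 0.827), nor did any of 20 genes for the apoptosome and caspases (median 0.10, camera adjusted p = 0.827). The apoptosome and caspase list also holds the inhibitors of apoptosis XIAP, BIRC2, BIRC3 and CFLAR. Its median and camera direction therefore pool members of opposite action. In that last list CASP2 was at 17 and 108 CPM in the DMSO libraries and 8.95 and 18.0 CPM in the Rib_GW libraries, and HTRA2, a mitochondrial protease, had a log2 fold change of 0.84 (SE 0.40). None of 11 death receptors and ligands passed (median -0.31, camera adjusted p = 0.776), and 2 rose and 2 fell when adjusted over the list alone. Without Rib_GW replicate 2, 2 anti-apoptotic genes rose, 2 apoptosome and caspase genes rose and 1 fell, and 4 death receptor genes rose and 2 fell. The TRAIL receptor TNFRSF10B had a log2 fold change of 1.35 (SE 0.31) and its ligand TNFSF10 one of -1.94 (SE 0.57).

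Among 25 p53 targets 2 rose, BBC3 and SESN2, 23 did not pass, the median was 0.28, and 7 rose when adjusted over the list alone. SESN2, a stress-induced inhibitor of mTORC1 signalling, rose from 13.2 ± 0.588 to 96.3 ± 5.82 CPM (n = 2 per group; log2 fold change 2.86, SE 0.26). The list was higher in camera (adjusted p = 0.00279), with an adjusted p = 0.653 with an estimated correlation. Leaving out DMSO replicate 2, Rib_GW replicate 1 and Rib_GW replicate 2 in turn gave 0, 5 and 11 rising members (and 2 falling in the last of these fits), with medians of 0.46, 0.29 and 0.44, and BBC3 was not called when either DMSO library was left out. The list median was 0.65 after the length and GC correction and 0.45 without a filter on low counts.

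The integrated stress response list was higher at camera's preset correlation. Of 29 ATF4 and integrated stress response genes (median log2 fold change 1.28), 10 rose and 19 did not pass, and adjusted over the list alone 24 rose and 1 fell. DDIT3, the transcription factor CHOP, rose from 9.33 ± 1.14 to 111 ± 49.9 CPM (n = 2 per group), though 27.2% of its exonic length overlaps a neighbour. TRIB3, a pseudokinase induced by ATF4, rose from 27.7 ± 5.62 to 295 ± 43.3 CPM, CHAC1, which degrades glutathione, from 2.59 ± 1.10 to 23.8 ± 3.11 CPM, and SESN2 was the other leading member. Both Rib_GW libraries lay above DMSO, with list medians of 1.48 and 1.33 relative to the DMSO mean. Camera gave an adjusted p = 1.97e-18, and an adjusted p = 0.583 with an estimated correlation. The rising members numbered 6 (with 1 falling) without DMSO replicate 1, 2 without DMSO replicate 2, 16 without Rib_GW replicate 1 and 24 without Rib_GW replicate 2. CHAC1 was not called without DMSO replicate 1, and DDIT3 and SESN2 were not called without DMSO replicate 2.

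In the unfolded protein response 2 of 23 genes rose and 21 did not pass (median 0.54), and 6 rose when adjusted over the list alone. HSPA5, the chaperone BiP of the endoplasmic reticulum, rose from 978 ± 71.6 to 3957 ± 74.3 CPM (n = 2 per group), and ERN1, the stress sensor IRE1, from 17.7 ± 0.362 to 75.5 ± 18.9 CPM. Camera gave an adjusted p = 6.69e-05, with an adjusted p = 0.583 with an estimated correlation, and this was the only list that fry called in 1 direction (adjusted p = 0.0126). In the heat shock response 2 of 15 genes rose, HSPA6 and DNAJB1, and 4 rose when adjusted over the list alone. DNAJB1, a co-chaperone, went from 198 ± 3.93 to 574 ± 48.3 CPM. The heat shock median was -0.01 while its mean was 0.47 and camera pointed up (adjusted p = 0.179, and 0.818 with an estimated correlation). That median was 0.37 without Rib_GW replicate 1 and -0.37 without Rib_GW replicate 2. Neither HSPA5, ERN1 nor DNAJB1 was called without DMSO replicate 1 or without DMSO replicate 2, and 6 and 10 unfolded protein response genes rose without Rib_GW replicates 1 and 2.

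Among 27 NRF2 and oxidative stress genes 1 rose, HMOX1, 26 did not pass (median 0.47), and 4 rose when adjusted over the list alone. HMOX1, which degrades haem, went from 13 ± 4.28 to 55.6 ± 5.94 CPM (n = 2 per group). The camera adjusted p = 0.0490 became an adjusted p = 0.758 with an estimated correlation. Among 4 metallothioneins (median 1.24) 1 rose, MT1X, from 26.6 ± 0.0266 to 93.6 ± 8.35 CPM, and 3 rose when adjusted over the list alone. Their camera adjusted p = 0.00245, with an adjusted p = 0.653 with an estimated correlation. HMOX1 and MT1X were not called without DMSO replicate 1 or without DMSO replicate 2. The NRF2 list was not called without DMSO replicate 1 (adjusted p = 0.101), DMSO replicate 2 (adjusted p = 0.0508) or Rib_GW replicate 1 (adjusted p = 0.327, median -0.08), and 12 of its members rose without Rib_GW replicate 2. It was also not called with limma-voom (adjusted p = 0.0790) or after the length and GC correction (adjusted p = 0.116, median 0.21), where the metallothioneins had a median of 0.63 (adjusted p = 0.0424).

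Both lists of lipid synthesis genes were lower at camera's preset correlation. Of 25 cholesterol synthesis genes (median -0.77) 1 fell, IDI1, and 24 did not pass, with 9 falling when adjusted over the list alone. IDI1, an isomerase of the isoprenoid pathway, fell from 187 ± 6.41 to 36.0 ± 4.63 CPM (n = 2 per group). Of 16 fatty acid synthesis genes (median -0.73) 1 fell, FADS2, a desaturase, from 476 ± 195 to 83.3 ± 10.8 CPM, with 7 falling when adjusted over the list alone. Camera gave an adjusted p = 1.53e-05 for cholesterol synthesis, with an adjusted p = 0.653 with an estimated correlation. It gave an adjusted p = 0.000223 for fatty acid synthesis, with an adjusted p = 0.594 with an estimated correlation. Without DMSO replicate 2 neither IDI1 nor FADS2 was called. Without DMSO replicate 1 there were 2 falling cholesterol genes, and without Rib_GW replicates 1 and 2 there were 9 and 6 falling cholesterol genes and 6 and 7 falling fatty acid genes, with 1 rising gene in each list without Rib_GW replicate 2.

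None of 34 lysosome genes passed over all genes or adjusted over the list alone (median 0.42), with the cholesterol transporter NPC1 at a log2 fold change of 1.48 (SE 0.28) and the glucosidase GAA at 1.18 (SE 0.26). The list was higher in camera (adjusted p = 0.00282), with an adjusted p = 0.758 with an estimated correlation. None of 28 autophagy genes passed (median 0.36), and 3 rose when adjusted over the list alone. MAP1LC3B, which encodes the autophagosome protein LC3B, was at 69.8 ± 12.3 and 299 ± 162 CPM (n = 2 per group; edgeR adjusted p = 0.0609), and WIPI1 had a log2 fold change of 1.15 (SE 0.27). Autophagy had a camera adjusted p = 0.0465 and an adjusted p = 0.594 with an estimated correlation. The lysosome list was not called without Rib_GW replicate 1 (adjusted p = 0.131, median 0.15), where 2 members rose, and had a median of 0.76 without Rib_GW replicate 2, where 15 rose and 2 fell. Autophagy was not called without DMSO replicate 2 (adjusted p = 0.0718, median 0.24), Rib_GW replicate 1 (adjusted p = 0.0526, median 0.24) or Rib_GW replicate 2 (adjusted p = 0.0648).

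All 46 cytosolic ribosomal protein genes of the fixed list had a positive log2 fold change, with a median of 1.11. None passed over all genes, and 35 rose when adjusted over the list alone. RPLP1 was at 238 ± 0.129 CPM in DMSO and 853 ± 377 CPM in Rib_GW (n = 2 per group; edgeR adjusted p = 0.0586), and RPS9 at 236 ± 43.3 and 730 ± 269 CPM (adjusted p = 0.0631). Many ribosomal protein genes have processed pseudogenes, so reads of single members are uncertain. The list was higher in camera (adjusted p = 8.87e-13), with an adjusted p = 0.653 with an estimated correlation. The listed ribosomal protein genes took 2.10 ± 0.433% of counts in DMSO and 4.58 ± 1.25% in Rib_GW. Across genes, the change after Rib_GW correlated with transcript length at a Spearman rho of -0.284 and with GC content at 0.257. The median length of the longest annotated transcript was 1985 bases in this list against 3653 over tested genes. The median was 0.69 without Rib_GW replicate 1, where 5 members rose, and 1.41 without Rib_GW replicate 2, where 34 rose, and 29 members rose with DESeq2, 10 without a filter on low counts and 3 after the length and GC correction.

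The 13 mitochondrially encoded mRNAs all had a negative log2 fold change, with a median of -1.79. None passed over all genes, and 12 fell when adjusted over the list alone. MT-ND1 was at 6780 ± 5425 CPM in DMSO and 1501 ± 420 CPM in Rib_GW (n = 2 per group; edgeR adjusted p = 0.0930), and MT-ATP8, which overlaps MT-ATP6, had a log2 fold change of -2.19 (SE 0.60). Mitochondrially encoded genes took 8.68% and 21.7% of counts in DMSO replicates 1 and 2 and 3.38% and 6.13% in Rib_GW replicates 1 and 2, and the 10 most abundant genes took 14.9 ± 8.16% and 7.62 ± 1.25%. The list was lower in camera (adjusted p = 1.99e-06), with an adjusted p = 0.653 with an estimated correlation. Its median was -0.92 without DMSO replicate 2, 6 members fell without DMSO replicate 1 and 2 without Rib_GW replicate 2, and DESeq2 called all 13 lower.

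None of 34 nuclear-encoded oxidative phosphorylation genes passed over all genes or adjusted over the list alone (median 0.60). NDUFV1, a subunit of respiratory complex I, had a log2 fold change of 1.13 (SE 0.27), and COX5B, a subunit of cytochrome c oxidase, one of 1.32 (SE 0.32). Camera gave an adjusted p = 0.00163, with an adjusted p = 0.758 with an estimated correlation. The median was 0.37 without DMSO replicate 2 and 0.27 without Rib_GW replicate 1, and 16 members rose without Rib_GW replicate 2. None of 30 ribosome biogenesis and MYC targets passed over all genes or adjusted over the list alone (median -0.18, camera adjusted p = 0.421), with UTP20 at -1.43 (SE 0.34) and WDR74 at 0.91 (SE 0.27). The median of that list was -0.10 without Rib_GW replicate 1, -0.29 without Rib_GW replicate 2, where 2 members rose and 8 fell, and -0.29 after the length and GC correction.

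The inflammatory cytokine list was higher at camera's preset correlation. Of 22 NF-kB and inflammatory cytokine genes (median 1.25) 2 rose, CXCL2 and IL1A, 20 did not pass, and 5 rose when adjusted over the list alone. IL1A, the cytokine interleukin 1 alpha, rose from 1.28 ± 0.103 to 12.7 CPM in both Rib_GW libraries (n = 2 per group; log2 fold change 3.31, SE 0.33). Camera gave an adjusted p = 1.93e-05, with an adjusted p = 0.653 with an estimated correlation. The list median relative to the DMSO mean was 1.98 in Rib_GW replicate 1 and 0.54 in replicate 2. The median log2 fold change was 0.37 without Rib_GW replicate 1, where 4 members rose and 1 fell, and 1.93 without Rib_GW replicate 2, where 16 rose. CXCL2 was not called when either DMSO library was left out, and IL1A was not called without DMSO replicate 2.

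The other signalling lists were not called. Of 28 immediate early and MAPK response genes 1 rose, DUSP1, a phosphatase of MAP kinases, from 46.6 ± 10.3 to 320 ± 50.7 CPM (n = 2 per group); adjusted over the list alone 3 rose and 3 fell. Their median was -0.31 although camera pointed up (adjusted p = 0.987). None of 31 interferon response genes passed (median -0.05, camera adjusted p = 0.426), 1 rose and 2 fell when adjusted over the list alone, and the antiviral genes OAS3 and GBP1 had log2 fold changes of -1.84 (SE 0.31) and -1.61 (SE 0.31). None of 18 antigen presentation genes passed (median 0.31, camera adjusted p = 0.426), 2 rose and 1 fell when adjusted over the list alone, and TAPBP had -1.22 (SE 0.31) while HLA-B, whose reads can be shared with its paralogs, had 1.56 (SE 0.40). None of 27 hypoxia and glycolysis genes passed over all genes or adjusted over the list alone (median -0.10, camera adjusted p = 0.612), with the glucose transporter SLC2A3 at 1.25 (SE 0.28) and the growth factor VEGFA at 1.41 (SE 0.34). Without Rib_GW replicate 2, so with 1 Rib_GW library and the spread of DMSO, antigen presentation had an adjusted p = 0.0131 with 10 members rising and 2 falling. In that fit 5 interferon genes rose and 6 fell, 4 hypoxia genes rose and 2 fell, and 4 immediate early genes rose and 5 fell.

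Of 17 genes of senescence-associated secretion 1 rose and 1 fell (median 0.63). For this list camera gave an adjusted p = 0.202, and 0.818 with an estimated correlation. Adjusted over the list alone 5 rose and 3 fell. GDF15, a stress-induced cytokine, rose from 8.71 ± 2.03 to 103 ± 33.4 CPM (n = 2 per group), and LMNB1, a nuclear lamin, fell from 124 ± 4.67 to 41.1 ± 2.03 CPM. LMNB1 is not secreted, but the list median and camera count it like the other members. LMNB1 was not called when either DMSO library was left out. The list was called without DMSO replicate 2 (adjusted p = 0.0246) and without Rib_GW replicate 2 (adjusted p = 0.0212). Its median was 0.38 without DMSO replicate 1 (adjusted p = 0.697), 0.23 without Rib_GW replicate 1 (adjusted p = 0.474) and 0.14 after the length and GC correction (adjusted p = 0.557). Of 33 EMT and extracellular matrix genes 3 fell and 30 did not pass (median -0.16). For the EMT list camera gave an adjusted p = 0.0802, and 0.818 with an estimated correlation. Adjusted over the list alone 2 rose and 4 fell. TGFB2, a growth factor, fell from 170 ± 24.2 to 33.0 ± 11.6 CPM, the matrix protein THBS1 from 443 ± 59.6 to 97.0 ± 17 CPM, and the protease inhibitor TIMP3 from 239 ± 8.29 to 52.4 ± 11.4 CPM. Without DMSO replicate 2 none of the 3 was called, and without DMSO replicate 1 the EMT list was called at an adjusted p = 0.00534 (median -0.46), as it was at 10 CPM (adjusted p = 0.0445) and with DESeq2 (adjusted p = 0.0479). The EMT median was -0.06 without DMSO replicate 2 and -0.32 without Rib_GW replicate 2, where 2 members rose and 8 fell.

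Markers of other cell types were measured beside these groups. Of 14 luminal breast epithelium markers 1 fell, SPDEF, an epithelial transcription factor, from 9.67 ± 2.46 to 1.42 ± 0.486 CPM (n = 2 per group), and it was not called without DMSO replicate 2. The luminal median was -0.06 (camera adjusted p = 0.725), and adjusted over the list alone 3 rose and 4 fell. None of 6 blood cell markers passed over all genes or adjusted over the list alone (median -0.10, camera adjusted p = 0.827), with CSF1R at 0.739 ± 0.279 and 0.283 ± 0.0390 CPM and LCP1 at 261 ± 10.9 and 390 ± 70.2 CPM. None of 5 fibroblast and endothelial markers passed over all genes or adjusted over the list alone (median -0.39, camera adjusted p = 0.265), with PECAM1 at 0.911 ± 0.309 and 0.203 ± 0.0347 CPM and PDGFRB at 2.26 ± 0.692 and 1.30 ± 0.0668 CPM. In all, camera at the preset correlation called 11 lists higher and 8 lower of the 33, and none was called with an estimated correlation. That version of the test had few residual degrees of freedom and little power. The unfolded protein response list had an estimated correlation of -0.038, below the preset 0.01, yet its camera p went from 1.82e-05 to 0.0418. Estimates for the CDK4/6-RB axis (-0.037) and autophagy (-0.032) were also below 0.01. In the other called lists they ran from 0.094 for p53 targets to 0.976 for mitochondrially encoded mRNAs, above the preset value. For those lists the p-values at the preset value may be too small. The lost calls by themselves neither show nor exclude that correlation between genes accounts for the calls at the preset value.

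**Figure D3:**
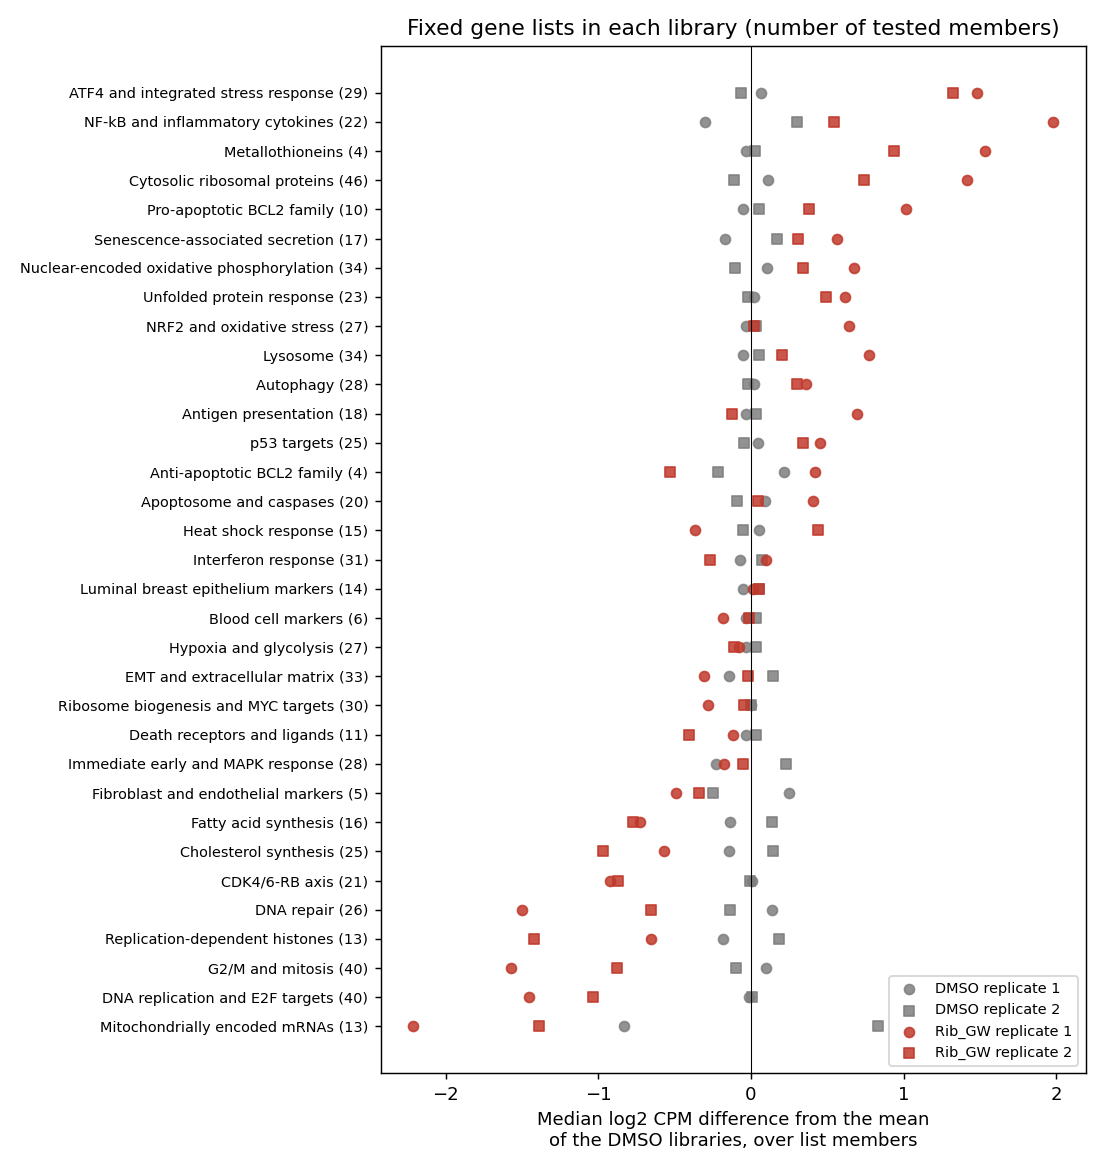
Median over the members of each fixed list of the log2 CPM difference from the mean of the DMSO libraries, with 1 point per library and the number of members in brackets. The ATF4 and integrated stress response list lies at 1.48 and 1.33 in the Rib_GW libraries, and the DNA replication list at -1.46 and -1.03.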

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

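The length and GC correction, the removal of mitochondrially encoded genes, the adjusted p of 0.10 and the crossed block were chosen after seeing the data, and the other alternatives were planned. All 203 called genes kept their direction in every refit that tested them (160 of them at the 10 CPM filter). The refits reuse the libraries in which these genes were called, so this is no independent support. Called genes higher and lower numbered 156 and 202 with RLE scaling, 195 and 174 with upper-quartile scaling, 523 and 404 without a filter, 1202 and 1111 with DESeq2, 450 and 441 after the length and GC correction, 203 and 212 without mitochondrially encoded genes, and 1059 and 791 at an adjusted p of 0.10. The filter at 10 CPM (106 and 86), limma-voom (94 and 99) and a 2-fold minimum (102 and 101) left the counts within 1.5 times. Leaving out 1 library, which leaves its group 1 library assumed to vary like the other group, gave 16 to 2280 genes higher and 12 to 2146 lower. Of the 42 called genes named by the fixed rule, 12 lost their call without DMSO replicate 1, 31 without DMSO replicate 2 and 5 with limma-voom, and none changed sign. Of 21 called genes examined outside it, 12 and 18 lost their call without DMSO replicates 1 and 2. Among lists with no called member, DESeq2 called 12 repair and 2 histone genes lower, 8 lysosome, 4 autophagy and 6 oxidative phosphorylation genes higher, and 1 apoptosome gene lower; higher and lower numbered 2 and 1 for death receptors, 2 and 4 for interferon, 3 and 1 for antigen presentation, 2 and 1 for hypoxia and 1 and 1 for ribosome biogenesis. Lists called higher and lower went from 11 and 8 to 0 and 0 with an estimated correlation. They stayed at 8 to 12 and 7 to 9 elsewhere. The test with an estimated correlation had few residual degrees of freedom. A fold of 2 was recovered for 12% of simulated genes, which limits what this depth and number of libraries can show. False calls, 21 of 173 in the simulation, were also a larger share than the threshold on adjusted p is set to allow. The cause of these shifts was not tested.

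With the replicate number as a block, 0 genes were called higher and 0 lower (3145 had an unadjusted p under 0.05 in edgeR). Deviations of same-numbered libraries correlated at -0.12, and no label says that the numbers pair the libraries. The crossed block, DMSO replicate 1 with Rib_GW replicate 2, called 1133 genes higher and 1089 lower. The pro-apoptotic family had a camera adjusted p = 0.0535 with the replicate block and 0.0478 with the crossed block.

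The median of the NRF2 list, called higher in camera, was -0.08 without Rib_GW replicate 1, where camera still pointed up. The other values that changed direction were of genes and lists not called. APAF1 was at -0.0348 with RLE scaling and with DESeq2 and -0.0122 without mitochondrially encoded genes, CYCS at -0.0132 with RLE scaling and with DESeq2, and BAX at -0.23 after the length and GC correction. The immediate early list was called neither way but pointed down in camera with medians of -0.35 with RLE scaling and DESeq2, -0.29 with upper-quartile scaling, -0.19 with limma-voom, -0.20 with the replicate block, -0.0742 after the length and GC correction and -0.33 without mitochondrially encoded genes. Blood cell markers pointed up with medians of -0.15 with DESeq2 and 0.16 without a filter. At 10 CPM, death receptors pointed up with a median of 0.0937 and luminal markers with one of 0.13. With a library left out, APAF1 ranged from -0.22 to 0.21, CYCS from -0.42 to 0.58, CASP9 from -0.42 to 0.57 and BCL2L2 from -1.37 to 3.34. List medians ranged from -0.61 to 0.40 for the anti-apoptotic family, -0.0118 to 0.39 for the apoptosome, -0.46 to -0.12 for death receptors, -0.37 to 0.37 for heat shock, -0.32 to 0.088 for interferon response, -0.17 to 0.82 for antigen presentation, -0.57 to 0.33 for the immediate early list, -0.0418 to 0.0851 for luminal markers and -0.27 to -0.0801 for blood cell markers. The direction turned without Rib_GW replicate 2 for death receptors, heat shock, interferon and luminal markers, without DMSO replicate 2 for blood cell markers, and without Rib_GW replicate 1 for the other lists, the immediate early list also turning without DMSO replicate 1. Other uncalled values moved by over 1.5 times but kept their sign in the fits named next. Without Rib_GW replicate 1, HTRA2 was at 0.15, COX5B at 0.86, HLA-B at 0.82, LCP1 at 0.34, MAP1LC3B at 1.35 and VEGFA at 0.89. Without DMSO replicate 2, CASP2 was at -0.38, MT-ATP8 at -1.10 and MT-ND1 at -1.01, and without DMSO replicate 1 PDGFRB was at -0.45. After the length and GC correction WDR74 was at 0.53, and list medians were -0.22 for hypoxia, -0.19 for interferon response, -0.37 for luminal markers and -0.30 for blood cell markers. The anti-apoptotic median was 0.78 without a filter, and at 10 CPM the interferon median was -0.31. The cause was not tested.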

Other observations

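The families, the single genes outside the fixed rule and the tests of the length and GC trend, of its spread within groups and of mixed RNA were chosen after the results were seen; the tests of depth, of the trend between the Rib_GW libraries and of the shared p53 targets were set out before. Among 10 gene families picked by symbol, 46 protocadherins, cell adhesion proteins of the cadherin superfamily, had a median log2 fold change of -0.94, with 41 negative and PCDH7 falling from 32.1 ± 2.54 to 7.71 ± 1.71 CPM (n = 2 per group). Camera gave the protocadherins an adjusted p = 9.22e-07, and an adjusted p = 0.425 with an estimated correlation. Family p-values here and below are adjusted over these 10 families alone. The families were picked from these same libraries, so their p-values describe the pick and give no independent support. Reads shared between members of this family were not examined and the counting program is not given, so the members may not be independent. The RNA-binding HNRNP family (20 of 22 negative, median -0.59) and the nucleoporins (21 of 22 negative, median -0.54) each had a camera adjusted p = 0.00169, and an adjusted p = 0.425 with an estimated correlation, and the HNRNP median was -0.33 without Rib_GW replicate 1. Of 78 mitochondrial ribosomal protein genes 64 were positive (median 0.44, camera adjusted p = 0.000983), with an adjusted p = 0.460 with an estimated correlation, and the median was 0.23 without Rib_GW replicate 1. The 8 SMAD genes (median -0.59, camera adjusted p = 0.00309) and 19 dual-specificity phosphatases (median 0.58, camera adjusted p = 0.00471) had an adjusted p = 0.425 with an estimated correlation, and the phosphatases were not called without Rib_GW replicate 1 (adjusted p = 0.0667, median 0.23). Aminoacyl-tRNA synthetases of cytosolic or dual location (here cytosolic synthetases) had a median of 0.20 over 20 genes. Camera gave them an adjusted p = 0.0329, and an adjusted p = 0.425 with an estimated correlation. They were not called without DMSO replicate 2 or Rib_GW replicate 2. Their medians were 0.36 without DMSO replicate 1, 0.13 without DMSO replicate 2 and 0.47 without Rib_GW replicate 1. The SR splicing factors (median -0.57), proteasome subunits (median 0.48) and mitochondrial synthetases (median 0.33) had camera adjusted p = 0.0636, 0.0636 and 0.223, and the proteasome was called without DMSO replicate 1 (adjusted p = 0.0326) and without Rib_GW replicate 2 (adjusted p = 0.0125), but not without Rib_GW replicate 1 (adjusted p = 0.430, median 0.21) or with an estimated correlation (adjusted p = 0.517). The mitochondrial synthetases had medians of 0.22 without DMSO replicate 2, 0.11 without Rib_GW replicate 1, 0.54 without Rib_GW replicate 2 and 0.21 after the length and GC correction. After the length and GC correction the mitochondrial ribosomal proteins (adjusted p = 0.104), the SMAD genes (0.0553) and the cytosolic synthetases (0.0553) were not called, the SR splicing factors, HNRNP genes, SMAD genes, mitochondrial ribosomal proteins and proteasome had medians of -0.26, -0.36, -0.38, 0.28 and 0.175, and PCDH7 was not called when either DMSO library was left out.

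Some called genes outside the lists are named here, and no enrichment was tested for them. SAT1, which acetylates polyamines for export and breakdown, rose from 24.7 ± 2.45 to 194 ± 82.5 CPM (n = 2 per group), and the spermine oxidase SMOX rose by a log2 fold change of 1.91 (SE 0.28). ASL and NAGS of the urea cycle rose by 2.06 (SE 0.30) and 1.94 (SE 0.29), and PYCR1 of proline synthesis by 1.87 (SE 0.26). The splicing factor SFPQ fell from 564 ± 112 to 111 ± 10.7 CPM, and the scaffold attachment factors SAFB and SAFB2 had log2 fold changes of -1.57 (SE 0.24) and -1.70 (SE 0.26). HES1, a target of Notch signalling, fell from 24.4 ± 10.0 to 2.97 ± 0.0461 CPM, the transcription factor SOX9 from 185 ± 86.3 to 25 ± 1.79 CPM, and the receptor LGR5 from 7.57 ± 1.72 to 0.315 ± 0.229 CPM. The read-through gene INO80B-WBP1 had 7.63 and 10.2 CPM in DMSO and 0 in both Rib_GW libraries while INO80B, which shares 72.0% of its exonic length with other genes, rose from 2.12 ± 0.782 to 18.9 ± 0.317 CPM. Of these genes, SMOX, ASL, NAGS, PYCR1, SAFB and SAFB2 were not called without DMSO replicate 1, and without DMSO replicate 2 only LGR5 and INO80B-WBP1 of them kept their call.

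Short and GC-rich transcripts were higher after Rib_GW. The longest annotated transcripts of ribosomal protein genes are short (median 1985 against 3653 bases), with a median GC content of 49.0% against 48.4% over tested genes. After the trend was removed from each library, the list median was 0.83 (quartiles 0.588 and 1.17) against 1.11 before, with 44 of 46 members above 0. This argues against a trend with length and GC of the longest annotated transcripts as the whole cause of the ribosomal protein rise. It cannot decide on a trend with the length of the transcripts expressed, which was not known. The corrected medians against the DMSO mean were 0.853 and 0.672 in the Rib_GW libraries and within 0.107 of 0 in the DMSO libraries. The rank correlation of the difference with GC content was -0.308 between the DMSO libraries and 0.386 between the Rib_GW libraries, so its size was at least 0.308 against 0.257 between groups, which is consistent with a library effect for GC. With transcript length it was 0.108 and -0.342 within groups against -0.284 between them. For length, a library effect and treatment therefore cannot be told apart. What remains open is a trend with the length of expressed transcripts, a change of ribosomal protein mRNA with treatment, as a hypothesis, and other differences between libraries.

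Rib_GW replicate 1 lay farther from the DMSO mean than replicate 2, at a median absolute log2 difference of 0.716 against 0.456. Depth is argued against, because replicate 2 thinned to the total of replicate 1 still lay at 0.637 times the distance of replicate 1. A trend with length and GC of the longest annotated transcripts removed 19.7% of the variance of the difference between the Rib_GW libraries. This argues against that trend as the whole cause. RNA of untreated cells mixed into replicate 2 would need 1 share for all lists, yet the median share was 0.604 (quartiles 0.376 and 0.746) for ribosomal proteins, 0.214 (0.0747 and 0.297) for DNA replication and -0.17 (-0.341 and 0.103) for cholesterol synthesis, beside 0.323 (0.205 and 0.455) for G2/M and 0.250 (0.00862 and 0.442) for ATF4. With the trend removed, ribosomal protein (0.274 and 0.679) and DNA replication quartiles (0.117 and 0.324) overlapped, as cholesterol and DNA replication quartiles did before it, while ribosomal protein and cholesterol quartiles (-0.338 and -0.0950 with the trend removed) were apart in both; a difference in exposure between the cultures stays open as untested, since no label describes them.

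The p53 target list was called higher at the preset correlation, but not with an estimated correlation (adjusted p = 0.653), and 6 of its 25 members also belong to other lists. Without them the median was 0.16 over 19 genes, no member was called in edgeR, and camera gave an adjusted p = 0.185 (adjusted p = 0.674 with an estimated correlation). The call was lost, and BBC3 and SESN2, the called members of the full list, are among the 6 removed. The median stayed above 0.1, the cutoff set beforehand for reliance on shared members, beside 0.04 over all tested genes. Whether the rise rests on shared members therefore cannot be told apart from a small rise of the remaining genes in 2 libraries per group.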
